A study of Mus musculus with 6 samples.

How the data were processed

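Total RNA from 6 cultures of RAW264.7 cells was labelled with biotin and hybridised to Affymetrix mouse arrays, 3 arrays for normal sodium and 3 for low sodium, per the labels. The deposited values were intensities on a linear scale, 1 per probe set and array, for 45101 probe sets. Partek is named in the submitters' processing notes without a version or a model, and the summarisation method is not given in the sources used here. The values themselves showed 1 scaling step, since the mean intensity between the 2nd and 98th percentiles was 499.8 on each array, which is what global scaling to a target of 500 gives. The median intensities were 70.2, 66.5 and 56.1 on the normal-sodium arrays and 74.5, 74.0 and 47.8 on the low-sodium arrays. The number of arrays limits the precision of every value.

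Intensities were put on a log2 scale after adding 1. Differences of dim probe sets depend on this added value, and that of Ifit3 went from -3.27 to -2.08 with 16 added instead. The 64 control probe sets of the manufacturer were left out of the tests, which ran on 45037 probe sets. Of these, 34945 carried 1 gene in the platform annotation, 932 carried several and 9160 carried none there, and those with several or none were not named. Entrez identifiers of 34754 probe sets were found in the RefSeq table of assembly GRCm38.p6, which was used for names only, and no coordinates are given because the files name no build. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays, chosen without the group labels. A set of 36 gene lists was written before the data were examined, and 727 of their 798 entries were matched to a measured gene.

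The design fixed before the data were examined was a comparison of low minus normal sodium on all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05). Gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list and with fry. The named-gene rule was fixed at the same time and had 3 parts. The first took the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with groups that did not overlap, a higher group mean at or above the median of all probe sets and no clone or predicted-gene symbol, and filled up with the smallest p where fewer than 10 passed. The second took up to 4 members of each list with the smallest p, and the third took a fixed list of osteoclast, transport and stress genes whatever their p, of which 12 were analysed here. Members behind a small count of a list were named as well, after their values had been seen.

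The spiked control transcripts separated the replicate 3 arrays of both groups from the others before any model was fitted. The planned test called 0 probe sets and 1 gene. A total of 14 models, the planned one among them, were counted on the probe sets, combining no block, the replicate number or a batch term (replicate 3 against replicates 1 and 2) with a constant or a trended prior, a pseudocount of 1 or 16, a filter on dim probe sets and replicates 1 and 2 alone. They called between 0 and 1840 probe sets, and 7 of them called 0. The fit with the batch term and the eBayes trend (called the batch-term fit in what follows) was taken up after these counts had been seen, and it gave the highest of them, the next being 563. The batch term was motivated by the spiked controls, while the trended prior was chosen with the counts in view. Its p-values therefore do not carry the same weight as those of a test fixed in advance, and the planned result is given beside its total counts. The accounts of gene lists other than mitosis give the batch-term fit, and planned calls of lists follow them. The batch term with a constant prior called 0 probe sets and 2 genes.

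The scripts were tested on simulated arrays of the 18193 genes with 200 genes changed in each of 3 simulations. The simulated values were drawn from the batch-term fit itself, with its batch shifts, its variances and independent noise. Changed genes came from the brighter 50% of genes, and their change was the same in both batches. The recovered shares therefore favour that fit by construction and do not test whether the real arrays follow it. For the comparison of low with normal sodium, the planned fit recovered 0% of genes changed by a log2 value of 1 and 41.7% of those changed by 2. The batch-term fit recovered 90.7% and 99% of them, with 5.17% of its calls false. With a constant prior the batch term recovered 6% and 81.3%, with 4.73% of calls false, so most of the gain at a log2 value of 1 came with the trended prior. Alternatives covered quantile normalisation, median centring, trended, robust and absent variance moderation, array weights, filters at the 25th and 50th percentiles, the replicate number as a block, another pseudocount, other ways to represent a gene and leaving out each array in turn. Quality measures were compared between the groups with exact two-sided permutation tests over 20 orders. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.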

Results

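RAW264.7 is a mouse monocyte-macrophage line that forms osteoclast-like cells under RANKL, the cytokine that drives osteoclast formation. Expression was measured after 24 hours in medium with sodium at 137 mmol/l (normal, 3 arrays) or 120 mmol/l (low, 3 arrays). Mannitol kept the osmolality of the low-sodium medium at 290 mOsm/l. The labels describe 4 biological replicates per group, and 3 per group were analysed here. M-CSF at 10 ng/ml and RANKL at 30 ng/ml are named beside the low-sodium medium in a wording that leaves open whether the normal-sodium cells received them, so each difference below is between the 2 media as labelled.

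The replicate 3 arrays of both groups stood apart from the other 4. Spiked Bacillus transcripts, added as labelling controls, averaged a log2 intensity of 10.21 on the arrays of replicates 1 and 2 and 8.35 on those of replicate 3, whereas hybridisation controls averaged 12.11 and 12.18. The 3′ probe set of the spiked dap transcript exceeded its 5′ probe set by a log2 value of 1.29 on the former and 3.11 on the latter. With the batches pooled, exact two-sided permutation p for low against normal sodium were between 0.5 and 1.0 for 6 such measures, where 0.1 is the smallest p that 3 against 3 arrays can give. Within each batch, however, the dap difference was higher in low sodium, at 1.25 and 1.46 against 1.23 and 1.22 in replicates 1 and 2 and at 3.28 against 2.94 in replicate 3, whereas that of the spiked phe transcript was higher in low sodium in replicates 1 and 2 (0.98 and 1.03 against 0.85 and 0.94) and lower in replicate 3 (2.24 against 2.48). Replicate 3 was therefore treated as a batch that holds 1 array of each group, and values are given within replicates 1 and 2 and within replicate 3.

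**Figure D1:**
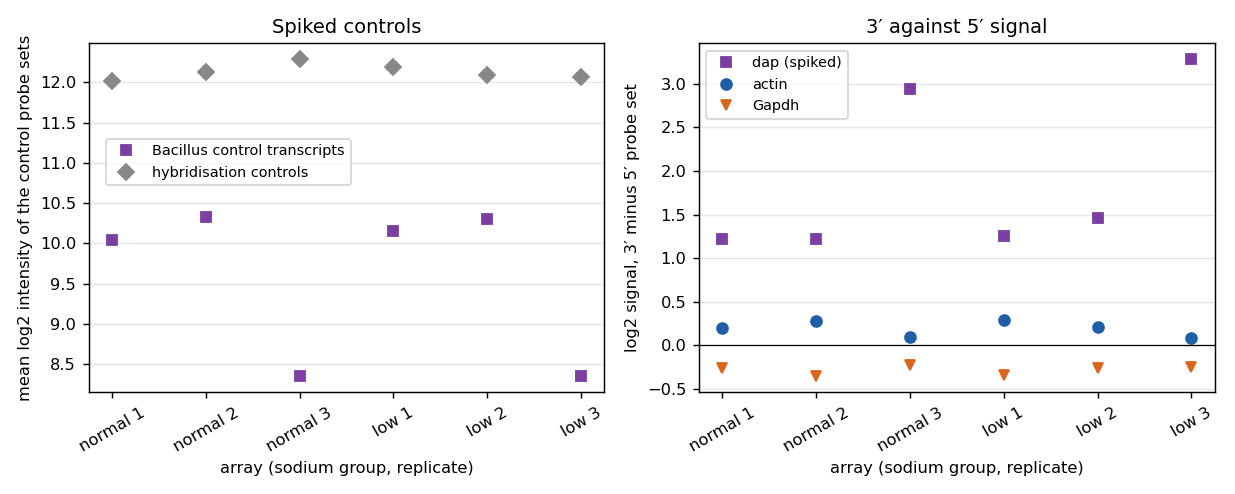
Control probe sets on each of the 6 arrays, 1 point per array. The left panel shows the mean log2 intensity of spiked Bacillus transcripts and of hybridisation controls, and the right panel the log2 signal of the 3′ minus the 5′ probe set of dap, actin and Gapdh. Bacillus controls average 8.35 in replicate 3 and 10.21 in the other arrays.

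The comparison asked how gene expression in these cells responds to low extracellular sodium. Dusp5, a phosphatase that inactivates ERK, rose 10.2-fold in low sodium, from a log2 intensity of 5.11 ± 0.17 to 8.46 ± 0.09 (SD, n = 3), and was the 1 gene that passed the planned limma test (adjusted p = 0.0468). Dusp5 lost that call under 5 alternative settings and without any 1 of the 6 arrays (adjusted p up to 0.415), and since its normal-sodium signal was dim its log2 difference of 3.35 became 2.88 with a pseudocount of 16. Mitosis genes fell as a list in the same planned fit, with a median log2 difference of -0.74 over 25 genes (camera adjusted p = 2.1e-21, adjusted p = 0.0401 with an estimated correlation). In the batch-term fit, chosen after the data were seen, 688 genes rose and 694 fell, among them the osteoclast genes Ctsk and Dcstamp, which rose, and the osmolyte transporter genes Slc6a12 and Slc5a3, which fell. Neither Ctsk nor Dcstamp passed the planned limma test (adjusted p = 0.805 and 0.612), and in both the groups overlapped. Slc6a12 and Slc5a3 did not pass it either (adjusted p = 0.153 and 0.133). The osteoclast genes Acp5, Calcr, Nfatc1, Oscar and Tnfrsf11a did not pass the batch-term fit, and Car2 fell.

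By the planned limma test 0 of 45037 probe sets passed, with 2868 at an unadjusted p under 0.05, and 1 of 18193 genes passed, with 1483 at an unadjusted p under 0.05. The batch term with a constant prior called 0 probe sets and 2 genes, Dusp5 and Slco4a1, and the batch-term fit with the trended prior called 1840 probe sets and 1382 genes. Of these genes 718 differed at least 1.5-fold and 233 at least 2-fold. Genes called in replicates 1 and 2 alone with a trended prior numbered 2705, of which 79.9% went the same way in replicate 3, against 55.1% of the genes not called. Most of the called genes were bright, and among the brighter 50% of genes the shares were 81.4% and 61.6%, while called genes that differed at least 2-fold went the same way in 74.0%. The count rests on the arrays used, since the batch-term fit called 463, 394 and 2663 genes without normal-sodium replicate 1, 2 or 3, and 418, 373 and 2682 without low-sodium replicate 1, 2 or 3. Without either replicate 3 array the batch term takes up the replicate 3 array that remains, so 2663 and 2682 rest on replicates 1 and 2. The batch-term fit takes the difference between the media to be the same in both batches. Across genes called in replicates 1 and 2, the differences in the 2 batches correlated at r = 0.45, and across the others at 0.03. List medians had the same sign in both batches for 27 of 36 lists. Whether the difference between the media itself differed between the batches cannot be settled, since replicate 3 holds 1 array per group.

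The rule for named genes took 10 genes higher and 10 lower in low sodium. Dusp5 alone of these passed the planned test, and the other 19 filled the rule by their p without passing it. All 20 passed the batch-term fit, to which the verbs and standard errors in the accounts of genes and gene groups refer. With a constant prior the batch term called 2 of the 20. The rule picked genes with small p and separate groups on the same arrays, so their calls are no separate support. Serpinb1a, an inhibitor of neutrophil serine proteases, rose by a log2 value of 3.88 ± 0.33 (SE, n = 3 against 3). Hbegf, a ligand of the EGF receptor, rose by 3.30 ± 0.24. Both were dim in normal sodium, and their differences were 3.47 for Serpinb1a and 3.00 for Hbegf with a pseudocount of 16. The remaining rises were 2.28 in Ahnak2, 2.00 in the chemokine gene Ccl6, 1.89 in the aminopeptidase gene Anpep, 1.78 in the macrophage gene Cd5l, 1.63 in Fam214b, 1.57 in Arhgap25 and 1.26 in the matrix gene Ecm1.

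Slc6a12, the betaine transporter gene, fell by 5.72 ± 0.47 on the log2 scale, from 10.36 ± 0.30 to 4.65 ± 1.16 (SD, n = 3), and its low-sodium signal was among the dim values. With a pseudocount of 16 in place of 1 its difference was -4.99. Slc6a13, a GABA and betaine transporter gene of the same family, had a difference of -1.99 ± 0.20, and Slc5a3, the inositol transporter gene, one of -1.75 ± 0.12. Slco4a1, an organic anion transporter gene, fell 10.1-fold, from 11.97 ± 0.35 to 8.63 ± 0.48. Fxyd2, whose product modulates the sodium pump, fell 4.84-fold. Car2, the carbonic anhydrase that supplies protons in osteoclasts, fell 7.96-fold, with log2 differences of -3.47 in replicates 1 and 2 and -2.04 in replicate 3. Ifit3, an interferon-induced gene, fell 9.64-fold, and since its low-sodium signal was dim (3.18 ± 0.45) its log2 difference of -3.27 became -2.08 with a pseudocount of 16. Cx3cr1 and Agmo had differences of -1.69 and -1.60. Fkbp11 had one of -1.43, and its 1 other bright probe set went the other way.

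**Figure D2:**
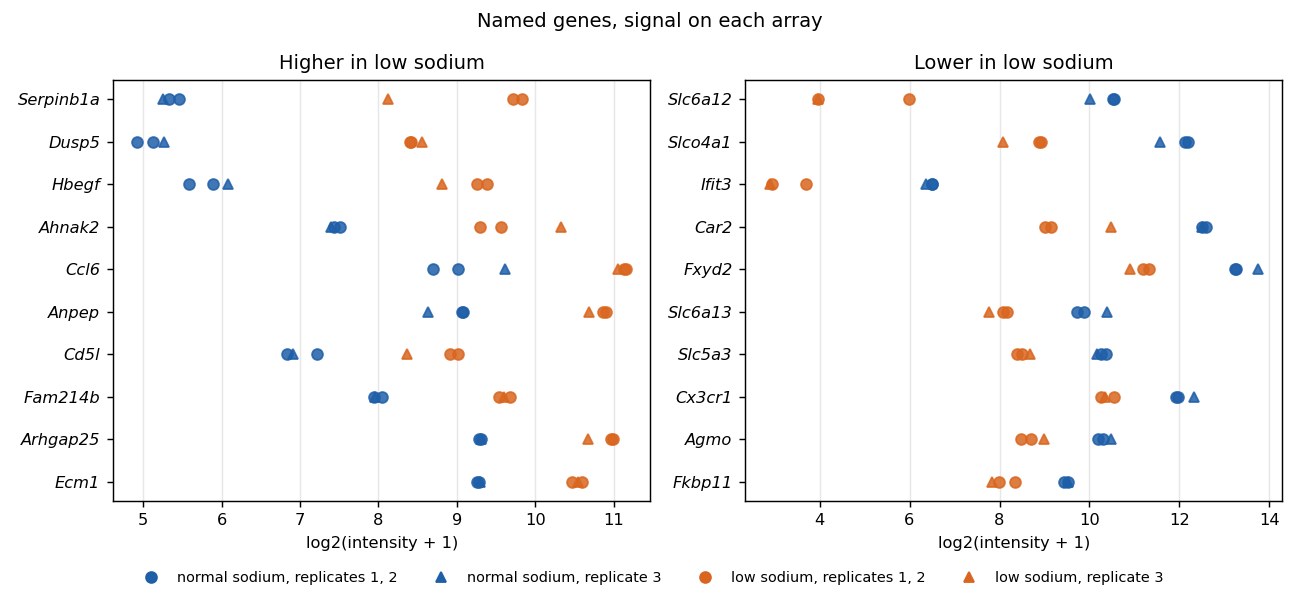
Signal of the 20 named genes as log2(intensity + 1), 1 point per array, with circles for replicates 1 and 2 and triangles for replicate 3. In the left panel all 3 low-sodium arrays lie above all 3 normal-sodium arrays, and in the right panel all lie below, as the naming rule required. Slc6a12 averages 10.36 in normal and 4.65 in low sodium.

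Of 21 measured osteoclast effector genes 9 rose, 11 did not pass and 1 fell, or 11 rose and 1 fell adjusted over the list alone, and the member that fell was Car2. Atp6v0d2, a proton pump subunit needed for osteoclast fusion, rose by 3.41 ± 0.51, and its difference was 2.45 in replicates 1 and 2 and 5.33 in replicate 3. Dcstamp, a fusion receptor gene, rose by 1.52 ± 0.15, the collagenase gene Ctsk by 1.15 ± 0.20 and the gelatinase gene Mmp9 by 1.05 ± 0.20. As a list they rose (camera adjusted p = 3.38e-06, adjusted p = 0.124 with an estimated correlation), with a median of 0.39 in replicates 1 and 2 and 0.51 in replicate 3. Clcn7 rose by 0.46, but 1 of its 2 other bright probe sets went the other way. Acp5, which encodes the acid phosphatase TRAP, differed by 0.70 ± 0.44 without passing (-0.04 in replicates 1 and 2, 2.17 in replicate 3). Oscar at -0.17 ± 0.31, Nfatc1 at -0.23 ± 0.14 and Tnfrsf11a, the RANK gene, at 0.12 ± 0.10 did not pass either. Calcr, the calcitonin receptor gene, was too dim in both media (3.09 and 3.64) for its difference to be read as a level, at 0.55 ± 0.72 and at 0.25 with a pseudocount of 16.

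Proton pump subunits rose in 9 of 16 genes and fell in 0, or in 13 and 0 adjusted over the list alone. Atp6v0a1 rose by 0.96, with 1 of its 3 other bright probe sets going the other way, the osteoclast subunit gene Tcirg1 by 0.84 and Atp6v1e1 by 0.56. The list rose (camera adjusted p = 1.03e-10, adjusted p = 0.171 with an estimated correlation), and its median was 0.27 in replicates 1 and 2 and 0.48 in replicate 3. Lysosome genes rose in 8 of 24 and fell in 0, or in 11 and 0 adjusted over the list alone, among them Npc1, Gpnmb, Ctsd and Gla by 0.38 to 0.52 (camera adjusted p = 1.96e-06, adjusted p = 0.230 with an estimated correlation, medians of 0.16 and 0.37 in the 2 batches). Of 25 RANK signalling and osteoclast transcription factor genes, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone. Fos rose by 0.64, Mitf by 0.59 and Junb by 0.40, and the list rose (camera adjusted p = 0.0294, adjusted p = 0.173 with an estimated correlation) with medians of 0.10 and 0.04 in the 2 batches. The RANK list had a median of 0.123 over all arrays, at percentile 97.16 of 10000 random lists matched on expression. This median lay just inside their central range, cut at the 2.5th percentile on each side (-0.154 to 0.126). Repressors of osteoclast formation rose as a list too (camera adjusted p = 0.00789, adjusted p = 0.171 with an estimated correlation), with medians of 0.24 and 0.15. Of 15 such genes 1 rose and 0 fell, or 5 and 0 adjusted over the list alone, and the 1 was Zfp36, whose product promotes the decay of cytokine mRNA, at 0.66 ± 0.07. Trem2 rose by 0.78, and its 1 other bright probe set went the other way.

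Of 11 measured tonicity-responsive genes, most of them targets of the transcription factor NFAT5, 0 rose, 6 did not pass and 5 fell, namely Slc6a12, Slc5a3, Slc38a2, Hspa1b and Nfat5 itself. Adjusted over the list alone, 1 rose and 5 fell. Nfat5 had a difference of -0.84 ± 0.20 (-0.48 in replicates 1 and 2, -1.56 in replicate 3), close to the threshold (adjusted p = 0.0493), and Sgk1 one of 0.62 ± 0.17 that did not pass. The list fell (camera adjusted p = 0.0092, adjusted p = 0.171 with an estimated correlation), although its median was -0.32 in replicates 1 and 2 and 0.16 in replicate 3. The list of sodium-coupled transporters shares Slc6a12, Slc5a3 and Slc38a2 with it. Of its 19 genes 3 rose and 4 fell, or 3 and 5 adjusted over the list alone, and the list was not called by camera (adjusted p = 0.261, medians of -0.14 and 0.11 in the 2 batches). Fry, which does not compare a list with other genes, called it lower (adjusted p = 0.0365). Outside the shared genes only Slc7a5 fell, and like Slc7a1 and Slc3a2, which rose, it belongs to amino acid transport that does not need sodium. The creatine transporter gene Slc6a8 rose by 1.37 ± 0.25 (0.91 in replicates 1 and 2, 2.29 in replicate 3). Among 23 sodium and cation transport genes 2 rose and 0 fell, also adjusted over the list alone, namely the potassium channel gene Kcnn4 by 0.81 and the phosphate transporter gene Slc20a1 by 0.92, and the list did not shift (camera adjusted p = 0.567, in the upward direction although the median was -0.09, with 0.17 and -0.16 in the 2 batches). The ascorbate transporter gene Slc23a2 differed by 0.55 ± 0.25 without passing. Slc23a1 was dim in both media and did not pass, with a difference of 1.36 ± 0.76 that became 0.77 with a pseudocount of 16.

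All 25 measured mitosis genes fell in the batch-term fit, also adjusted over the list alone, and 20 of them passed the planned test adjusted over the list alone. Bub1b had a difference of -1.02 ± 0.08, Aurkb one of -0.93 ± 0.07, Plk1 one of -0.85 ± 0.07 and Aurka one of -0.83 ± 0.07. The list median was -0.70 in replicates 1 and 2 and -0.83 in replicate 3 (camera adjusted p = 4.33e-29, adjusted p = 0.124 with an estimated correlation). DNA replication genes fell in 8 of 26 and rose in 0, or in 17 and 0 adjusted over the list alone. Tk1 had a difference of -0.99 ± 0.09 and Rrm1 one of -0.62 ± 0.08, and the list fell (camera adjusted p = 2.66e-09, adjusted p = 0.230 with an estimated correlation), with a median of -0.28 in replicates 1 and 2 and -0.85 in replicate 3. Of 16 p53 target and arrest genes 5 rose and 0 fell, or 8 and 2 adjusted over the list alone. Plk2 rose by 2.15 ± 0.19 and Cdkn1a, the gene of the cyclin-dependent kinase inhibitor p21, by 0.62 ± 0.11 (camera adjusted p = 0.00103, adjusted p = 0.317 with an estimated correlation), and the list median was 0.22 in replicates 1 and 2 and 1.02 in replicate 3. The medians of DNA replication genes and p53 targets were further from 0 in replicate 3, but with 1 array per group there a difference between the batches cannot be told from array variation.

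Immediate early genes and regulators of MAP kinase signalling rose in 11 of 26 and fell in 0, or in 15 and 0 adjusted over the list alone. Beside Dusp5, Dusp1 rose by 1.20, Klf2 by 0.86 and Myc by 2.01. The list rose (camera adjusted p = 4.55e-09, adjusted p = 0.124 with an estimated correlation), with medians of 0.59 and 0.51 in the 2 batches. Chemokine and receptor genes rose in 7 of 20 and fell in 2, or in 9 and 3 adjusted over the list alone (camera adjusted p = 0.000132, adjusted p = 0.124 with an estimated correlation, medians of 0.64 and 0.51). Ccl6 rose by 2.00, Ccr2 by 1.13 and Ccl9 by 0.59, and Cx3cr1 and Cxcl16 fell. Macrophage markers rose in 8 of 25 and fell in 0, or in 12 and 1 adjusted over the list alone (camera adjusted p = 3.57e-06, adjusted p = 0.124 with an estimated correlation, medians of 0.44 and 0.39), among them Mertk by 1.47 and Adgre1, the gene of F4/80, by 0.96. Matrix and protease genes rose in 5 of 18 and fell in 0, also adjusted over the list alone, led by the urokinase gene Plau at 2.75 ± 0.30 (camera adjusted p = 0.00118, adjusted p = 0.171 with an estimated correlation, medians of 0.91 and 0.33).

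Of 24 MYC target and ribosome biogenesis genes 2 rose, 9 fell and 13 did not pass, or 2 rose and 16 fell adjusted over the list alone, and the 2 that rose were Myc and Odc1. Cad had a difference of -0.92 ± 0.11 and Ddx21 one of -0.65 ± 0.08, and the list fell (camera adjusted p = 2.98e-07, adjusted p = 0.124 with an estimated correlation, medians of -0.25 and -0.30 in the 2 batches). Of 20 unfolded protein response genes 2 rose, 7 fell and 11 did not pass, or 3 rose and 11 fell adjusted over the list alone. Pdia4 and Sdf2l1 had differences of -0.83 and -0.59, whereas Ern1, the gene of the stress sensor IRE1, rose by 1.07 ± 0.16 with 1 of its 2 other bright probe sets going the other way (camera adjusted p = 0.00379, adjusted p = 0.169 with an estimated correlation, medians of -0.22 and -0.31). Cholesterol synthesis genes fell in 3 of 20 and rose in 0, or in 4 and 0 adjusted over the list alone (camera adjusted p = 4.77e-06, adjusted p = 0.334 with an estimated correlation), but their median was -0.62 in replicates 1 and 2 and 0.10 in replicate 3. In replicates 1 and 2 alone with the trended prior, 16 of the 20 fell and 0 rose. Hmox1, the heme oxygenase gene, rose by 0.67 ± 0.13.

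The smaller shifts covered metabolism, stress and signalling. Calcium signalling genes rose in 8 of 25 and fell in 0, or in 10 and 3 adjusted over the list alone, among them Camk2d by 1.03 and the calcineurin gene Ppp3ca by 0.49 (camera adjusted p = 0.00163, adjusted p = 0.148 with an estimated correlation, medians of 0.18 and 0.32 in the 2 batches). Of 22 inflammatory genes 2 rose and 0 fell, also adjusted over the list alone, namely Il1rn, the gene of the interleukin-1 receptor antagonist, by 1.57 and Tnf by 1.21 (camera adjusted p = 0.0209, adjusted p = 0.204 with an estimated correlation, medians of 0.36 and 0.02). Mitochondrial biogenesis genes fell in 3 of 14 and rose in 0, or in 5 and 0 adjusted over the list alone, with Mrpl12 at -0.49 ± 0.07 (camera adjusted p = 0.000186, adjusted p = 0.124 with an estimated correlation, medians of -0.29 and -0.25). Among 27 ATF4 target and amino acid response genes 5 rose and 3 fell, or 8 and 3 adjusted over the list alone. Trib3 rose by 1.70 and Psat1 had a difference of -0.77 (camera adjusted p = 0.00759, adjusted p = 0.457 with an estimated correlation). The ATF4 list had a median of 0.06 in replicates 1 and 2 and 0.50 in replicate 3, and it was not called in replicates 1 and 2 alone (camera adjusted p = 0.349). NRF2 targets had a median of 0.34 in replicate 3 and 0.01 in replicates 1 and 2, with 4 of 20 that rose and 1 that fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0085, adjusted p = 0.465 with an estimated correlation). They were not called in replicates 1 and 2 alone either (camera adjusted p = 0.545). Autophagy genes (2 of 17 rose and 1 fell) and podosome genes (5 of 29 rose and 1 fell) were higher as lists, with camera adjusted p = 0.0123 and 0.00118, and with medians in the 2 batches of 0.14 and 0.12 for autophagy and 0.28 and 0.03 for podosomes. Heat shock genes (0 of 12 rose and 1 fell, Hspa1b), oxidative phosphorylation genes (0 of 37 rose and 1 fell, Atp5o) and cytosolic ribosomal proteins (0 of 21 rose or fell) were lower, with camera adjusted p = 0.0068, 0.00118 and 0.0384, and none of these 5 lists passed with an estimated correlation (lowest adjusted p = 0.171). The medians in the 2 batches were -0.18 and -0.04 for heat shock, -0.08 and -0.02 for ribosomal proteins and -0.14 and 0.01 for oxidative phosphorylation. Adjusted over the list alone 4 autophagy genes rose and 1 fell, 7 podosome genes rose and 1 fell, and the counts of the other 3 lists stayed as they were. The median over all arrays was at percentile 6.59 of 10000 random lists matched on expression for heat shock and 5 for oxidative phosphorylation. It was at 25.9 for ribosomal proteins and 93.98 for autophagy. All of these lay inside the central range, so such medians do not set these lists apart from random ones. Podosome genes (97.96) lay outside it, as did every other list called by the batch-term fit except RANK signalling. In replicates 1 and 2 alone with the trended prior, 13 of the 37 oxidative phosphorylation genes fell and 0 rose. Interferon response genes did not shift as a list (camera adjusted p = 0.973, medians of 0.30 and -0.38), with 0 of 27 that rose and 1 that fell, Ifit3, also adjusted over the list alone.

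**Figure D3:**
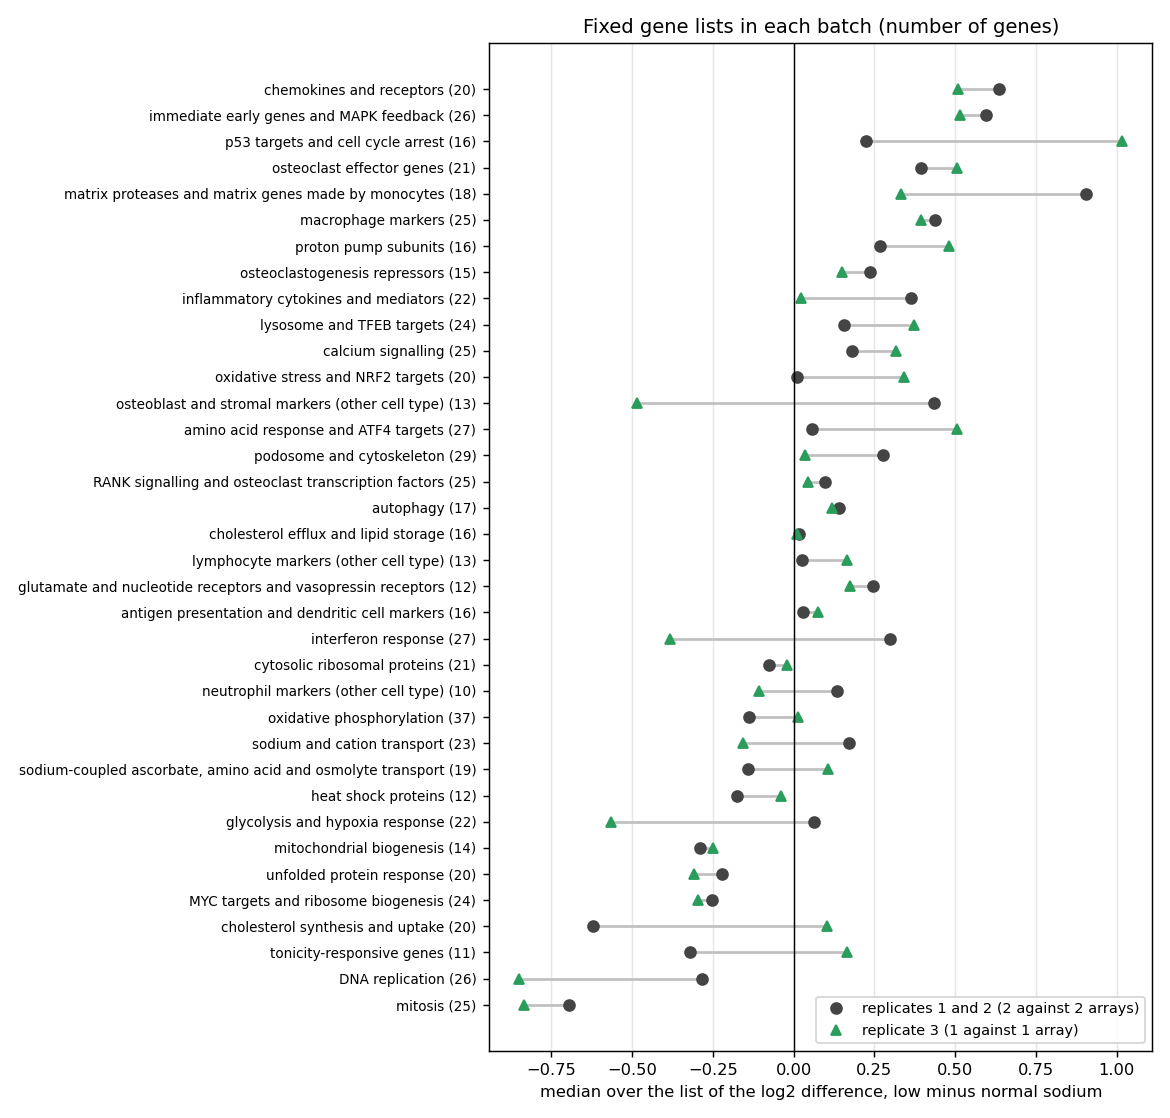
Median over each fixed gene list of the log2 difference between low and normal sodium, with circles for replicates 1 and 2 and triangles for replicate 3, and the number of measured genes in brackets. Mitosis genes lie at -0.70 and -0.83, and cholesterol synthesis genes at -0.62 and 0.10.

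Over the 36 lists, the planned fit called 10 higher and 6 lower with the preset correlation, and the batch-term fit 16 higher and 10 lower. Called by the batch-term fit but not the planned fit were RANK signalling (planned camera adjusted p = 0.0897), osteoclast repressors (0.0801) and unfolded protein response (0.0798). The same held for NRF2 targets (0.169), calcium signalling (0.0509), inflammatory genes (0.0929) and autophagy (0.152). It also held for heat shock (0.0897), oxidative phosphorylation (0.119) and cytosolic ribosomal proteins (0.405). With an estimated correlation the planned fit kept 1 list, mitosis, and the batch-term fit kept 0 (lowest adjusted p = 0.124), with 9 lists at an unadjusted p under 0.05 in the latter. Fry, with the batch term and trend, called 22 lists. It tests whether genes of a list move one way without comparing them with other genes. Its calls included sodium-coupled transporters (adjusted p = 0.0365, lower) and antigen presentation (0.0134, higher), which camera did not call. Lists called by camera but not by fry were cholesterol synthesis (fry adjusted p = 0.132), p53 targets (0.0686) and ATF4 targets (0.158). The same held for NRF2 targets (0.127), oxidative phosphorylation (0.218) and cytosolic ribosomal proteins (0.105). Markers of other cell types gave no calls over all genes, with 0 of 13 osteoblast and stromal, 0 of 13 lymphocyte and 0 of 10 neutrophil genes past the batch-term fit, 1 neutrophil gene that rose adjusted over the list alone, and list-level camera adjusted p of 0.973 for each. In the planned test 1 osteoblast and stromal gene passed adjusted over the list alone. Only 3, 5 and 3 genes of these lists had a higher group mean at or above the median of all values. The others were dim, so a lack of calls says little about them.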

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

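The tests of replicate 3 given here were chosen after the result was seen.

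The 18S ribosomal RNA control probe sets, which the comparison of genes did not use, drew attention because every low-sodium array lay above every normal-sodium array. The difference was 0.64 on the log2 scale for the 3′ probe set and 0.45 for the 5′ probe set, and 0.37 for the middle one, whose groups overlapped. Of 19 mouse control probe sets 2 had all low-sodium arrays above and 0 all below, where chance gives 5% for each direction. Groups of 3 arrays were not examined for outlying arrays.

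The replicate 3 arrays of both groups stood apart in the spiked controls. Degraded RNA or short cDNA would raise the 3′ over the 5′ signal, which for actin changed by -0.15 on the log2 scale. The actin probe sets lie near the top of the scale, where such a rise would be compressed, and for the spiked transcripts it went from 1.29 to 3.11 for dap and from 0.95 to 2.36 for phe, so this explanation stays open. A different culture was tested by the 3747 genes that differed between replicate 3 and the others, but a labelling step could change these too. The spiked Bacillus transcripts do not come from the cells. Their mean log2 intensity was 10.21 in replicates 1 and 2 and 8.35 in replicate 3, with hybridisation controls at 12.11 and 12.18. These values argue that the spiking or labelling differed. Whether the cells or the state of their RNA differed as well stays open.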

How the results depend on the processing

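The alternatives with a batch term, and those applied to the batch-term fit, were chosen after seeing the data. The planned fit called 0 probe sets, 1 gene and 16 lists. Probe sets passing numbered 33 with a trended prior, 9 with no variance moderation, 1 with array weights, 2 after the filter at the 50th percentile and 1 with a pseudocount of 16. With the batch term they numbered 1840 with the trend, 563 with the filter, 1720 with the trend and pseudocount 16, whereas replicates 1 and 2 alone, without a batch term, gave 3714 with the trend and 0 with a constant prior. Genes passing numbered 0 with quantile normalisation, median centring, the robust prior, the replicate block and the probe set with the largest variance, 40 with the trend, 10 without moderation, 120 with array weights, 11 with the filter and 4 with pseudocount 16. With the batch term they numbered 2 with a constant prior, 1382 with the trend, 844 with the filter, 1297 with the trend and pseudocount 16, and replicates 1 and 2 alone with the trend gave 2705. Leaving out 1 array gave 0 to 3 genes, with 3 without low-sodium replicate 3 and 0 without any other array. Dusp5 lost its call without each array and under the 5 settings that gave 0 genes (adjusted p up to 0.415), though its log2 difference stayed between 3.26 and 3.43 in the arrays left out in turn. Lists numbered 26 with the batch term and trend, 25 with the batch term and filter, 26 with pseudocount 16 as well, 1 with an estimated correlation, 0 with the batch term and an estimated correlation, and 5 by fry. The 1382 genes of the batch-term fit became 659 with median centring, 2376 with array weights, 844 with a constant prior and the filter, 2 with a constant prior, 2705 in replicates 1 and 2 alone with the trend, 822 with the mean of a gene's probe sets and 761 with the probe set of largest variance. Leaving out 1 array gave 373 to 2682 genes: 463, 394 and 2663 without normal-sodium replicate 1, 2 or 3, and 418, 373 and 2682 without low-sodium replicate 1, 2 or 3. Its 26 lists became 0 with an estimated correlation and 24 to 26 without 1 array. Some genes changed sign with the probe set of largest variance: Fkbp11 0.36, Oscar 0.61, Clcn7 -0.014, Slc20a1 -0.68, Atp5g1 0.65, Ppargc1a 0.072, Rrm1 0.88, Gins1 0.016, Mdm2 -1.46, Rps6 0.52, Tnfaip2 -0.49 and Dock5 -0.28. With the mean of probe sets these were Oscar 0.22, Atp5g1 0.20, Mdm2 -0.094, Rps6 0.12 and Dock5 -0.026, and in replicates 1 and 2 alone Acp5 -0.036 and Camp 0.092. Without 1 array Nfatc1 ranged from -0.41 to 0.015 and Oscar from -0.44 to 0.14. In the batch-term fit without either replicate 3 array (2663 or 2682 genes), the batch term takes up the replicate 3 array that remains. Those counts therefore rest on replicates 1 and 2, which alone gave 2705. Apart from this, and from the smaller number of tests after a filter and of arrays when some were left out, the cause was not tested. Over all named genes and alternatives 3108 values kept direction and side of the threshold, 452 passed where the planned fit did not, 11 lost the call and 22 changed sign. Signal over background limits what the dim probe sets can show, since the median of all intensities was 64.4, and Slc6a12 moved from -5.72 to -4.99 with pseudocount 16.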

Other observations

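The tests of mitosis genes within replicates 1 and 2, of the other probe sets of the tonicity genes and of mannitol were chosen after the result was seen, as was the batch-term fit.

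Genes differed between the replicates as well as between the media. Between replicate 3 and the other arrays, 1747 genes were higher and 2000 lower in replicate 3 by limma. Cholesterol synthesis genes were higher there in 17 of 20 and lower in 0, oxidative phosphorylation genes higher in 31 of 37 and lower in 1, and DNA replication genes lower in 15 of 26 and higher in 0. The median difference of cholesterol synthesis genes, low minus normal sodium, was -0.62 in replicates 1 and 2 and 0.10 in replicate 3. Since replicate 3 holds 1 array per group, these values cannot show whether the response itself differed between the batches.

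Mitosis genes fell in low sodium, and 3 technical explanations were tested. Scaling between arrays is argued against by a median of -0.74 relative to all genes after quantile normalisation. Signal level is argued against because the 2.5th percentile of 10000 random lists matched on expression was -0.14. An origin in the replicate 3 arrays alone is argued against by a median of -0.70 in replicates 1 and 2. Slower division of cells in low sodium would fit these values, and no cell counts were analysed here.

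Tonicity-responsive genes fell as a list in the batch-term fit although the osmolality was kept with mannitol (adjusted p = 0.171 with an estimated correlation), with a median of -0.32 in replicates 1 and 2 and 0.16 in replicate 3. The 5 members that fell were the transporter genes Slc6a12, Slc5a3 and Slc38a2 with Hspa1b and Nfat5. Relative to all genes the 5, which were chosen for being lower, had a median of -1.10 before and -1.11 after quantile normalisation, and the whole list one of -0.40 both times, which argues against scaling between arrays as the whole cause. Of their other bright probe sets 100% were lower (9 of 9, most of them for Nfat5 and Hspa1b and none for Slc6a12), but some hardly differed. Those of Slc38a2 were at -0.06 and -0.53, and those of Nfat5 ranged from -0.13 to -1.21. Those of Hspa1b were at -1.20 and -1.36, and the 1 of Slc5a3 at -1.31. This argues against one faulty probe set for Hspa1b and Slc5a3, less firmly for Nfat5 and Slc38a2, and leaves it open for Slc6a12. Mannitol or another part of the diluted medium stays open, since 0 arrays of cells in normal sodium with mannitol were analysed.

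The arrays were also regrouped in other ways, and these splits are too few for a share under 0.05. Each other split also mixes the 2 media within its groups, so a difference between the media widens the spread there. Low counts in the other splits therefore do not measure how many calls are false. Under the planned fit, 10 of 10 splits gave as many probe sets as the real 0 (highest other 0), which a real count of 0 makes certain. For genes 1 of 10 splits gave as many as the real 1 (highest other 0), and for lists 1 of 10 as many as the real 16 (highest other 13). Under the batch-term fit, 1 of 6 splits balanced over the batches gave as many genes as the real 1382 (highest other 0) and 1 of 6 as many lists as the real 26 (highest other 14). The other 5 balanced splits called 7 to 14 lists each with the preset correlation.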
